A study of Arabidopsis thaliana with 9 samples.

How the data were processed

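One-colour long-oligonucleotide expression arrays (9 samples, 3 per group) were analysed, each hybridised with Cy3-labelled total RNA from Arabidopsis thaliana leaves. The 3 groups were wild-type leaves at stage S1 (WT_S1), transgenic leaves at stage S1 (LEC2_S1) and transgenic leaves at stage S3 (LEC2_S3). Wild-type leaves at stage S3 were not analysed here. The labels call the 3 arrays of each group biological replicates.

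Per the file headers and the labels, the arrays were NimbleGen arrays read at 1 wavelength, and the deposited probe files hold the spot brightness as intensity on a linear scale. The header of the scanner files names NimbleScan version 2.5.26 as the extraction software. Each array held 389307 spots. Of these, 364416 were spots of 182208 probes for 30386 genes, with each probe printed in 2 blocks, and 24891 were random control spots. There were 6 probes for 30354 of the genes and fewer for 32. Log2 intensity of the 2 blocks correlated across probes at 0.992 or higher on each array. The table of processed values deposited by the authors holds 1 intensity per gene and array, and the submitters' processing notes name RMA (robust multi-array averaging). No header or label gives a genome build for the probes, so no coordinates are printed.

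The file of WT_S1 replicate 2 had another layout than the other 8. Only 10.1% of its values were whole ninths, against 98.1% or more on the other arrays. Its sorted log2 values lay at a median distance of 0.0997 from the mean of the other 8 arrays after background correction and sorting. Their correlation was 0.999, which sorted values reach easily, so it decides little. The lowest value of the file was 10.39 and its median random probe 60.74, against 69.67 and 181.89 or more on the other 8. The file was therefore taken to hold spot values already corrected and scaled, and it entered the normalisation through its ranks. A comparison of gene values with the authors' deposited table gave a correlation of at least 0.999 between each array and its own column, except for WT_S1 replicates 2 and 3. Each of these matched its own column at 0.987 and the other's at 0.999. Both belong to WT_S1, so no group changed, but their replicate numbers are uncertain.

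From the scanner intensities, the RMA convolution background was removed from the 8 raw files, and all 9 arrays were quantile normalised to the mean distribution of those 8. The 2 blocks of a probe were averaged on the log2 scale, and the probes of a gene were summarised by median polish. A gene counted as above background on an array when its value was over the 95th percentile of that array's random control probes. Genes above background on at least 3 of the 9 arrays were tested, which gave 17631 genes and left out 12755. Where a gene was not above background on any array of 1 group, the ratio is given as "at least N-fold". That bound is the mean of the brighter group against the mean, over the dim group's arrays, of the higher of the gene's own value and the lowest value above background on that array. No fold is given where this bound is under 1 or where both groups were below background.

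The fit used limma (version 3.58.1, R 4.3.3) with lmFit and eBayes on all 9 arrays, which leaves 6 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method within each of the 3 comparisons, with a threshold of 0.05. Two-sided tests were used throughout. Counts are also given for genes that passed and differed at least 2-fold. Gene lists were fixed before the data were examined: 26 lists with 422 members, all on the array, of which 352 were tested. A list of shoot meristem markers had no tested member. Counts of list genes in the text refer to tested members. A gene not above background in the wild type could be tested only through its transgenic arrays. Members below background throughout were left out, so the shares and camera p-values of the seed lists depend in part on this filter. Lists were tested with camera at a preset correlation of 0.01 between genes, adjusted over 75 tests (25 lists in 3 comparisons), and again with an estimated correlation and with fry. Every list call was lost with the estimated correlation, with adjusted p-values of 0.069 or higher.

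The genes named in the text follow a rule also fixed before the data were examined. It takes LEC2, the 6 largest rises and the 6 largest falls with a symbol and no overlap between the 3 arrays of each group, and up to 2 members of each list with the largest changes. Where no member of a list passed, the rule takes the 2 smallest p-values, given as values only. Other genes named from the lists or from counts of 5 or fewer were chosen after their values were seen. Names come from the reference table of assembly TAIR10.1, in which 29997 of the 30386 array genes had an entry and 10358 a symbol other than the locus name. Near-identical genes can share probe signal, so values of the paired HSD1 loci, the AT14A pair, the 2S albumins (SESA) and the CAB genes are uncertain for each single locus.

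The test was tried on simulated data with the same 17631 genes and spread. Only a small share of the genes was changed in each simulation. In the real data 28.1% of tested genes passed in LEC2_S3 against LEC2_S1 and 23.5% in LEC2_S3 against WT_S1. Recovery depends on the share of changed genes, so the simulated values may not carry over to those comparisons. For LEC2_S1 against WT_S1, 4.48% of genes changed 1.5-fold were recovered, 20.9% of those changed 2-fold and 83.3% of those changed 4-fold. For LEC2_S3 against LEC2_S1 the shares were 1.49%, 31.3% and 83.3%, and for LEC2_S3 against WT_S1 1.49%, 25.4% and 81.8%. Each comparison rested on a single simulated data set with the same spread in every group. Differences between the comparisons may therefore be sampling noise, and the weaker signal of the S3 arrays was not simulated. The number of arrays limits the precision.

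File names place the arrays in 4 scan batches. One held WT_S1 replicates 1 and 3 with LEC2_S1 replicates 2 and 3, another held WT_S1 replicate 2 with LEC2_S1 replicate 1, and the S3 arrays lay in 2 batches of their own (replicates 1 and 3, and replicate 2). Genotype at S1 could thus be tested with batch as a block, whereas S3 arrays shared no batch with S1 arrays. Per the file headers, the image names of LEC2_S1 and LEC2_S3 also carry different codes, and whether these stand for different transgenic lines is not given in the sources used here. The alternatives tried were other background corrections (normexp with offset 50, none), other normalisations (median scaling, cyclic loess, centring on the tested genes), a mean in place of median polish, the authors' deposited values, other filters on dim genes, other forms of eBayes, array weights, single pairs of groups, each replicate left out, and blocks for replicate number and scan batch.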

Results

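LEC2 (LEAFY COTYLEDON2) encodes a B3-domain transcription factor that directs seed maturation in the embryo. In the transgenic plants it was placed under the promoter of AtNAP, a gene that is switched on in senescing leaves. Transcripts were measured in leaves of the Columbia-0 ecotype on 9 arrays, 3 each for wild-type leaves at stage S1, transgenic leaves at S1 and transgenic leaves at S3. At S1 the plants were 40 days old and the leaves 100% green, and at S3 more than 50% of the leaf was yellow. On the S1 arrays 16727 to 17687 genes were above background. On the S3 arrays the numbers were 13976, 15845 and 14181 for replicates 1, 2 and 3. In the scanner values, the median gene probe of S3 replicates 1 and 3 was 3.57 and 3.34 times the median random probe, against 6.01 to 8.81 on the other arrays with raw signal. S3 replicate 2 stood at 7.63. Against the 95th percentile of the random probes, however, the median gene probe stood at 0.868, 1.22 and 0.898 on S3 replicates 1, 2 and 3 and at 1.54 or more on the S1 arrays with raw signal, so by this measure replicate 2 was weaker too. No S3 array shared a scan batch with an S1 array, so batch and stage cannot be told apart.

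**Figure D1:**
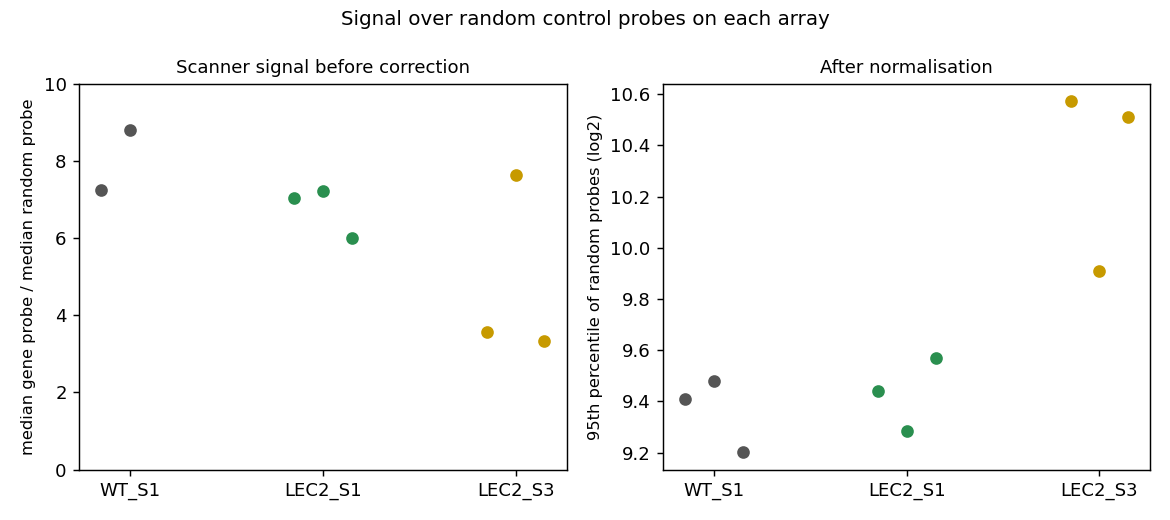
Left, median signal of gene probes divided by that of random control probes on the 8 arrays with raw scanner signal. Right, 95th percentile of the random control probes (log2) after normalisation on all 9 arrays; points are arrays, and S3 replicates 1 and 3 stand at 10.57 and 10.51 against 9.20 to 9.57 at S1.

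In the summary over its 6 probes, LEC2 itself (AT1G28300) was not above background on any wild-type array, at log2 levels of 7.51, 8.27 and 7.25. It reached 11.83, 13.68 and 13.24 in the green transgenic leaves and 14.38, 14.50 and 13.89 in the yellow ones. The rise over the wild type was at least 11.7-fold at S1 (log2 fold change 5.24, SE 0.47, adjusted p = 0.00247, n = 3 per group, limma) and at least 29.7-fold at S3 (6.58, SE 0.47, adjusted p = 1.95e-04). These bounds hold for the summary and not for every probe: 2 of the 6 probes lay above the wild-type thresholds in WT_S1, at mean log2 levels of 10.87 and 9.89, and the first of them rose only to 11.86 in LEC2_S1. Between the stages LEC2 was 2.54-fold higher at S3 in the fitted means, which did not pass the threshold (log2 fold change 1.34, SE 0.47, adjusted p = 0.063, limma). In 7 other background, scaling, summary or weighting settings it passed, with log2 fold changes of 1.35 to 1.96, and without LEC2_S1 replicate 2 it also passed (1.73, adjusted p = 0.0471). In the other settings it did not pass, among them the fit without LEC2_S1 replicate 1 (0.80, adjusted p = 0.149), the authors' processed values (adjusted p = 0.0523), the 6 arrays of the 2 groups alone (adjusted p = 0.0919) and scan batch as a random block (adjusted p = 0.104). Whether the LEC2 probes separate transcripts of the transgene from those of the resident gene was not tested. At S1 the log2 fold change was 6.08 within the scan batch with 2 arrays of each genotype and 3.55 within the batch with 1 of each, and with batch as a block its adjusted p was 0.022 (0.00247 without the block).

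**Figure D2:**
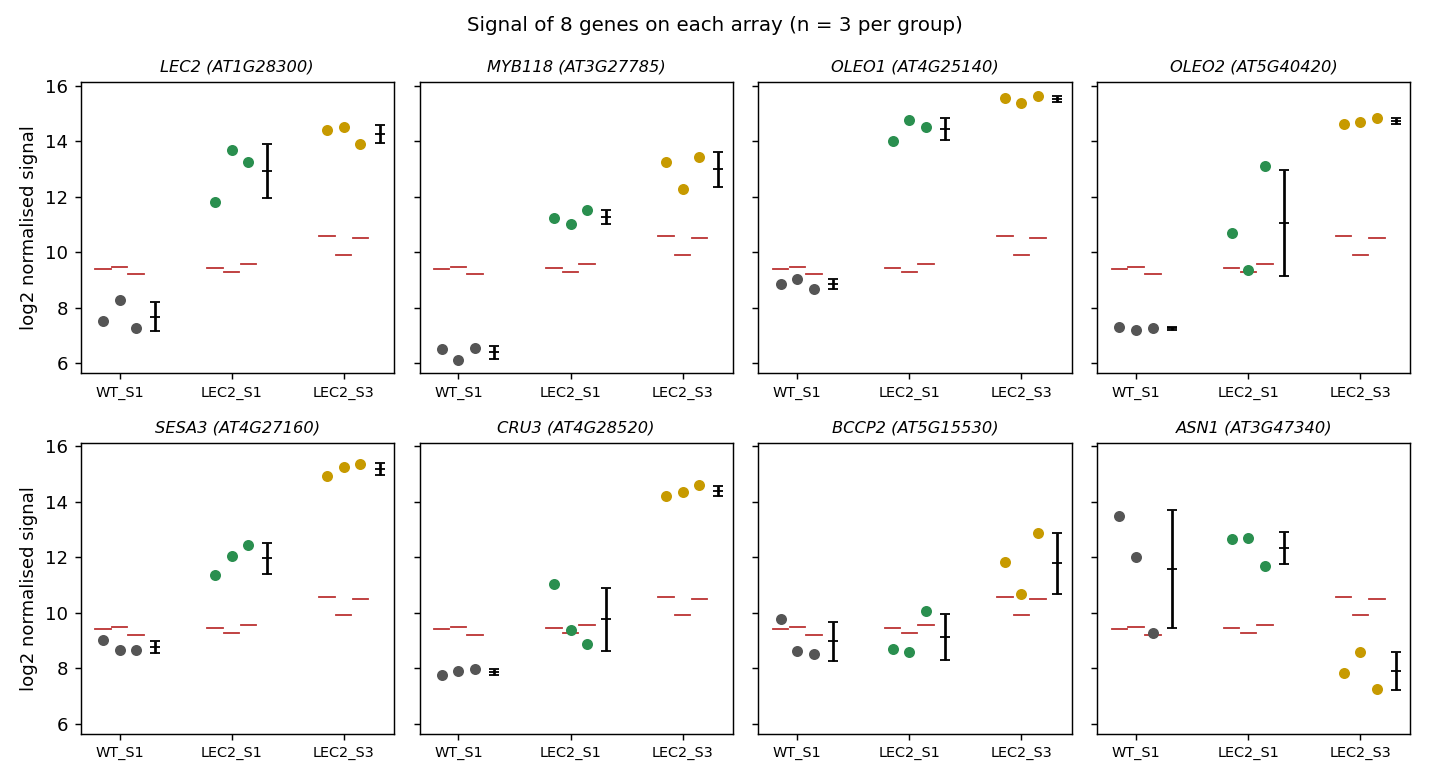
Log2 normalised signal of 8 genes; coloured points are single arrays, black bars the mean and SD of 3 arrays, and red lines each array's background threshold. LEC2, MYB118, OLEO1 and SESA3 lie above the threshold on all 6 transgenic arrays and on no wild-type array, while ASN1 lies below it on the 3 S3 arrays.

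The comparison of LEC2_S1 with WT_S1 asks which transcripts differ with the transgene while leaves are still green. Genes of seed oil bodies, seed storage and seed regulation were among the rises. The largest fitted log2 fold changes were those of AT3G30833, annotated as a pseudogene (9.11), and AT5G38160 (8.14), both without a symbol, not above background in the wild type and named after their values were seen. OLEO1 (AT4G25140), which encodes an oleosin that coats oil bodies, rose at least 33.6-fold (log2 fold change 5.58, SE 0.21, adjusted p = 1.45e-05). MYB118 (AT3G27785), a regulator of seed maturation, rose at least 3.71-fold (4.86, SE 0.31, adjusted p = 2.65e-04). The paired loci AT5G50600 and AT5G50700, which encode the oil-body steroleosin HSD1, rose at least 2.41-fold and 2.75-fold. CYP704B1 (AT1G69500), a cytochrome P450 known from pollen wall formation, rose at least 4.2-fold (log2 fold change 6.46, SE 0.45, adjusted p = 5.46e-04) and was not above background in the wild type.

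In the list of seed storage proteins, 3 of 11 tested members rose, and 9 did when adjusted over the list alone. SESA3 (AT4G27160) and SESA5 (AT5G54740), both 2S albumins, rose at least 6.05-fold and at least 1.72-fold; SESA5 was above background on 2 of the 3 LEC2_S1 arrays. In the list of oil body proteins 3 of 11 rose, and again 9 adjusted over the list alone. Camera placed both lists above other genes, with adjusted p-values of 5.09e-11 and 5.80e-11 at the preset correlation, but adjusted p = 0.093 and 0.15 with an estimated correlation. Of 9 tested seed maturation regulators, which include LEC2, only LEC2 and MYB118 passed, and 3 did adjusted over the list alone (camera adjusted p = 3.18e-05, and adjusted p = 0.29 with an estimated correlation). PER1 (AT1G48130), a seed peroxiredoxin, passed among 9 desiccation genes but lay below background in both groups.

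Within the scan batch holding 2 arrays of each genotype, the median log2 fold changes of the oil body and storage lists were 2.00 and 1.61. They were 1.34 and 2.21 within the batch holding 1 of each. No tested gene of plastid fatty acid synthesis (33), triacylglycerol assembly (22), lipid breakdown (21), leaf senescence (31), chlorophyll breakdown (8) or photosynthesis (51) passed over all genes. FAE1 (AT4G34520), which elongates seed fatty acids, had a log2 fold change of 2.40 (adjusted p = 0.244), and ORE1 (AT5G39610), a senescence regulator, 2.75 (adjusted p = 0.16). Camera at the preset correlation placed senescence genes (median 0.62, adjusted p = 0.00403) and autophagy genes (median 0.28, adjusted p = 4.38e-04) above other genes. It placed photosynthesis (median -0.18, adjusted p = 1.32e-05), jasmonate (median -0.95, adjusted p = 4.02e-05) and fatty acid synthesis genes (median -0.19, adjusted p = 0.00198) below them. With an estimated correlation these gave adjusted p = 0.84, 0.84, 0.96, 0.56 and 0.93. Markers of xylem and secondary wall moved with these groups: their median was -2.32 in 3 tested genes, all 3 lower adjusted over the list alone (camera adjusted p = 0.00205, and adjusted p = 0.43 with an estimated correlation).

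The genes that fell at S1 numbered 3. PPT2 (AT3G01550), a plastid phosphoenolpyruvate transporter, fell 4.36-fold (SE 0.28 on the log2 scale, adjusted p = 0.0329). RR5 (AT3G48100), a cytokinin-induced response regulator also called ARR5, fell 3.56-fold (SE 0.18, adjusted p = 0.00494), and the other was AT1G09575, named after its value was seen. In all, 37 of 17631 tested genes passed in limma, 34 higher and 3 lower, each at least 2-fold, and 2166 had an unadjusted p under 0.05. The 3 arrays of one genotype did not overlap those of the other in 23.9% of tested genes, against 10% by chance.

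The excess of rises depends on the fit. With scan batch as a block 142 genes passed, 52 higher and 90 lower, with 32 of the 37 among them, and in a fit of the 6 S1 arrays alone 200 passed, 88 higher and 112 lower, with 33 of the 37. Within the batch of 2 arrays per genotype 9 passed, all higher, and the batch with 1 array of each gave no test; leaving out WT_S1 replicate 1, 2 or 3 left 24, 22 and 23 genes.

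**Figure D3:**
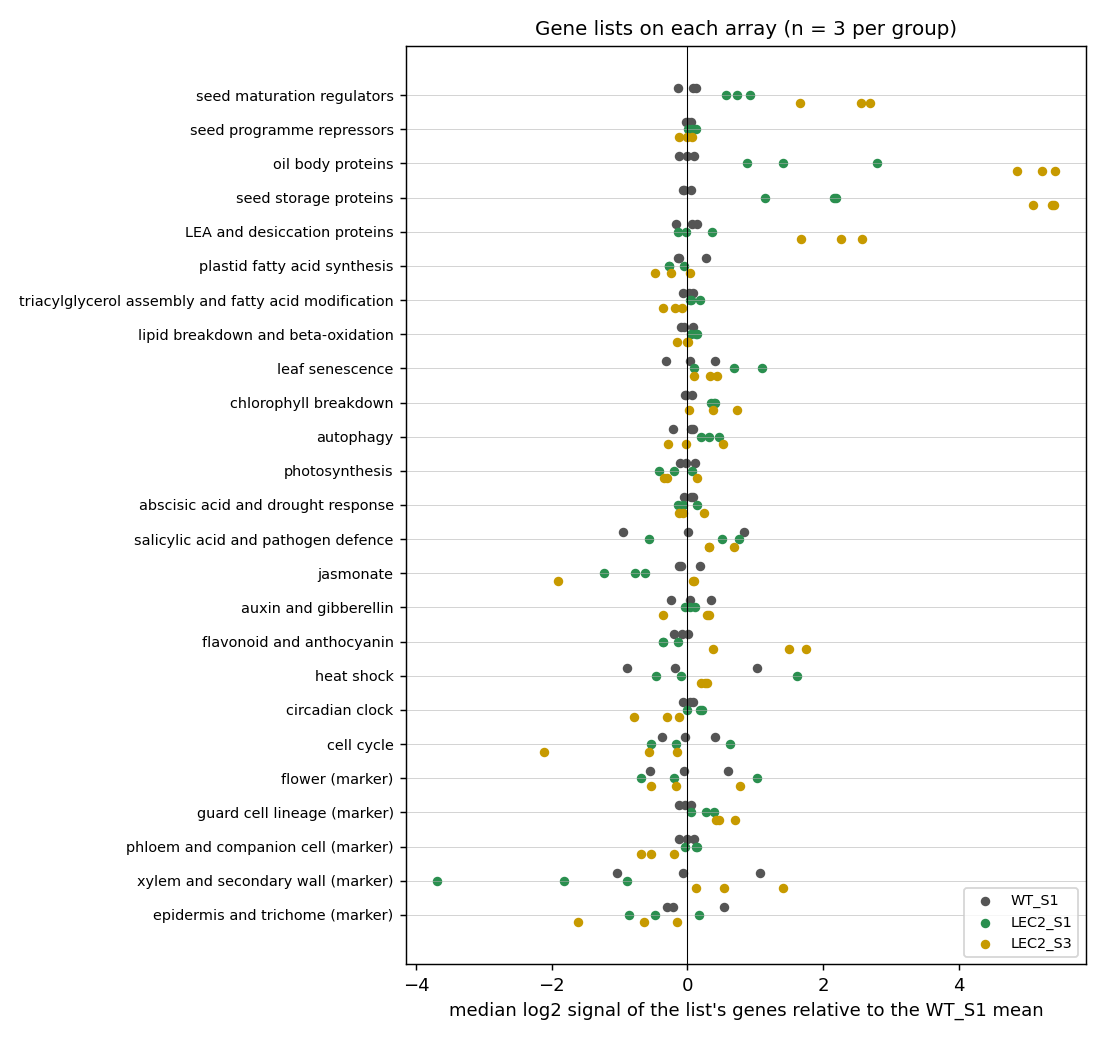
Median log2 signal of the tested genes of each list on each array, relative to the WT_S1 mean; points are arrays, 3 per group. The oil body and storage lists are higher on every LEC2_S1 array than on any WT_S1 array and higher again on the S3 arrays, whereas the photosynthesis list spans 0 in each group.

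The comparison of LEC2_S3 with LEC2_S1 sets yellow against green transgenic leaves. The image names of the 2 groups carry different codes whose meaning is not given, so different transgenic lines at the 2 stages are not excluded. All 11 tested storage protein genes and all 11 oil body genes rose. The 12S globulin genes CRU3 (AT4G28520) and CRA1 (AT5G44120) rose 24.7-fold (log2 SE 0.47, adjusted p = 0.00191) and 19.8-fold (SE 0.40, adjusted p = 0.00139). CRU2 (AT1G03880), another 12S globulin, rose at least 7.13-fold, and SESA1 (AT4G27140) 23.0-fold. CRU3, CRA1 and SESA1 were above background on 2 of the 3 LEC2_S1 arrays. The caleosin gene CLO1 (AT4G26740, ATS1 in the reference) rose at least 6.99-fold, OLEO4 (AT3G27660), above background on 2 of 3 LEC2_S1 arrays, 14.3-fold, and the seed-specific gene ATS3 (AT5G07190) at least 6.52-fold. Camera adjusted p-values were 2.02e-14 for storage and 5.80e-11 for oil bodies, with adjusted p = 0.069 and 0.15 with an estimated correlation.

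Among 9 tested seed maturation regulators of 15 listed, which include LEC2, 5 rose and 1 fell. AGL15 (AT5G13790), a MADS-box gene of embryos, rose 7.69-fold (adjusted p = 0.0208; above background on 1 of 3 LEC2_S1 arrays), and BZIP67 (AT3G44460) at least 2.78-fold. FUS3 (AT3G26790), another B3 regulator of seed maturation, had a log2 fold change of 1.88 (adjusted p = 0.0161), and ABI5 (AT2G36270), which acts in abscisic acid signalling in seeds, was the member that fell, at least 1.97-fold (adjusted p = 0.0417). Of 15 listed desiccation genes 9 were tested and 6 of these rose, PER1 by at least 4.99-fold and LEA76 (AT3G15670) by at least 6.92-fold. Camera gave adjusted p = 4.38e-04 and 9.83e-06 for these lists, and adjusted p = 0.41 and 0.15 with an estimated correlation. Of 14 listed flavonoid genes 8 were tested and 4 of these rose (camera adjusted p = 2.41e-04, and adjusted p = 0.32 with an estimated correlation). Among them were the anthocyanin regulators PAP1 (AT1G56650), 6.29-fold higher, and PAP2 (AT1G66390), 5.97-fold higher. PAP2 was above background on 1 of 3 LEC2_S1 arrays.

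Lipid enzymes went both ways, as did the tested genes as a whole (1370 of 17631 higher and 3584 lower). Camera did not set the lists of fatty acid synthesis, triacylglycerol assembly and lipid breakdown apart from other genes (adjusted p = 0.522, 0.746 and 0.952 at the preset correlation). In plastid fatty acid synthesis 3 of 33 rose and 5 fell, and the 2 largest changes were BCCP2 (AT5G15530), a subunit of acetyl-CoA carboxylase, 6.32-fold higher (adjusted p = 0.0174), and the acyl carrier protein ACP1 (AT3G05020), 5.38-fold higher (adjusted p = 0.00729). BCCP2 and FAE1 were above background on 1 of 3 LEC2_S1 arrays. In triacylglycerol assembly 2 of 22 rose and 5 fell. FAE1 rose 8.22-fold (adjusted p = 0.0141), while ROD1 (AT3G15820), which moves polyunsaturated fatty acids into triacylglycerol, fell 2.45-fold (adjusted p = 0.0176). In lipid breakdown, malate synthase (MLS, AT5G03860) rose at least 2.69-fold and 5 of 21 genes fell, among them SDP1L (AT3G57140), a triacylglycerol lipase homologue that was not above background at S3 (adjusted p = 0.00629).

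In the yellow leaf 6 of 31 senescence genes fell and none rose. ASN1 (AT3G47340), asparagine synthetase, which is induced in darkness, fell at least 4.04-fold, and SEN1 (AT4G35770) fell 10.1-fold (SE 0.42 on the log2 scale, adjusted p = 0.0035). The list as a whole did not stand apart (median -0.13, camera adjusted p = 0.952). HCAR (AT1G04620), an enzyme of chlorophyll turnover, fell 2.55-fold (adjusted p = 0.00914) and was the 1 gene of 8 in chlorophyll breakdown to pass. Of 21 autophagy genes 2 rose and 4 fell, and of 51 photosynthesis genes 3 rose and none fell, with CAB3 (AT1G29910) 1.83-fold and PSAD1 (AT4G02770) 1.57-fold higher. The photosynthesis list had a median of 0.05 (camera adjusted p = 0.0299, and adjusted p = 0.98 with an estimated correlation).

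Of 13 clock genes, LHY (AT1G01060) rose 2.87-fold (adjusted p = 0.00882) and CCA1 (AT2G46830) also rose, while ELF3 (AT2G25930) fell 5.26-fold (adjusted p = 0.00139) and GI, LUX and PRR5 fell. In hormone lists, IAA19 (AT3G15540) rose 4.83-fold and GH3.5 (AT4G27260), which conjugates auxin, fell 5.10-fold (above background on 1 of 3 S3 arrays), and the jasmonate receptor gene COI1 (AT2G39940) fell 2.93-fold. COR15A (AT2G42540), a cold and drought gene, fell 3.58-fold (above background on 2 of 3 S3 arrays), and ABA2 (AT1G52340), an abscisic acid synthesis gene, rose 2.22-fold. No defence gene of 20 passed. Falls outside the lists included CYP704B1 (at least 2.15-fold), AT14A (AT3G28290, 37.5-fold), the cold regulator CBF1 (AT4G25490, at least 3.22-fold), BGLU18 (AT1G52400, 12.2-fold) and HFR1 (AT1G02340, at least 3.05-fold), which acts in light signalling. CYP704B1, CBF1 and HFR1 were above background on no S3 array, AT14A on 1 and BGLU18 on 2. Markers of other cell types moved too: the xylem genes CESA4 (AT5G44030) and CESA7 (AT5G17420) rose at least 1.75-fold and 2.57-fold and were above background on 2 of 3 S3 arrays (list camera adjusted p = 0.0141, and adjusted p = 0.58 with an estimated correlation), and the phloem genes SWEET12 (AT5G23660) and APL (AT1G79430) fell 2.04-fold and 1.47-fold, and the epidermal gene PDF1 (AT2G42840) rose 2.07-fold.

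Altogether 4954 of 17631 genes passed, 1370 higher and 3584 lower, and 2371 of them at least 2-fold, 800 higher and 1571 lower (limma). The median tested gene was at -0.20, and with each array centred on the median of the tested genes, a setting chosen after the data were seen, 1847 were higher and 2483 lower, or 1032 and 1016 at 2-fold. Among genes above background on all 9 arrays 502 were higher and 567 lower at 2-fold. Without LEC2_S3 replicate 1 or 3, 2022 and 2121 genes passed, without LEC2_S3 replicate 2 7659, and without LEC2_S1 replicate 1 or 2 2014 and 2646. With replicate 2 as the only S3 array, assumed to vary like the other groups, 72 genes passed, 30 higher and 42 lower.

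The comparison of LEC2_S3 with WT_S1 joins the transgene with the change of stage, which cannot be separated without yellow wild-type leaves. All 11 storage genes and 10 of 11 oil body genes rose. HSD1 (AT5G50700) rose at least 16.1-fold, OLEO2 (AT5G40420) at least 40.9-fold, OLEO1 at least 71.4-fold, SESA3 at least 56.9-fold, CRU3 at least 32.7-fold and MYB118 at least 12.3-fold. The medians of the 2 lists were 5.31 and 5.24 on the log2 scale, with camera adjusted p = 3.82e-18 and 6.29e-16, and adjusted p = 0.069 and 0.13 with an estimated correlation. Of the 9 tested regulators 6 rose, the transgene LEC2 among them, and none fell (camera adjusted p = 2.12e-07, and adjusted p = 0.15 with an estimated correlation). The regulator list was not tested without LEC2, so its result restates the transgene in part. Of 9 desiccation genes 5 rose, PER1 at least 5.23-fold and M10 (AT2G41280) at least 10.8-fold, and 1 fell (camera adjusted p = 4.42e-05, and adjusted p = 0.15 with an estimated correlation).

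FAE1 rose at least 3.84-fold, BCCP2, above background on 1 of 3 WT_S1 arrays, 7.04-fold, ACP1 5.71-fold and MLS at least 2.82-fold, against 6 falls among the 33 fatty acid synthesis genes and 4 among the 21 of lipid breakdown. Camera did not set the lists of fatty acid synthesis and lipid breakdown apart from other genes (adjusted p = 0.626 and 0.952 at the preset correlation). Among repressors of the seed programme, VAL1 (AT2G30470) rose 3.23-fold and the Polycomb component MSI1 (AT5G58230) fell 2.08-fold. Senescence genes were split, with 4 higher and 4 lower of 31: SAG13 (AT2G29350) rose 13.2-fold (adjusted p = 0.0177; above background on 2 of 3 WT_S1 arrays) and DIN11 (AT3G49620) fell at least 1.25-fold (adjusted p = 0.0235). In autophagy 4 of 21 rose, among them ATG8G (AT3G60640) 2.49-fold and ATG8F (AT4G16520) 2.02-fold, and 2 fell (list median -0.02). Of 51 photosynthesis genes 2 rose and 1, LHCB1.4 (AT2G34430), fell 2.31-fold. ALD1 (AT2G13810), a gene of pipecolate synthesis in defence, rose 6.75-fold (above background on 2 of 3 WT_S1 arrays), and 4 of 8 flavonoid genes rose, with PAP2 at least 4.48-fold higher (camera adjusted p = 0.00448, and adjusted p = 0.48 with an estimated correlation).

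Falls included AT14A (50.1-fold), the cytokinin-induced response regulator ARR6 (AT5G62920, at least 4.77-fold), BT2 (AT3G48360, at least 2.52-fold), PAP3 (AT1G14700), the cell wall gene XTH4 (AT2G06850, 18.4-fold) and KCS8 (AT2G15090, 16.6-fold), which elongates very long fatty acids. AT14A, XTH4 and KCS8 were above background on 1 of 3 S3 arrays, and PAP3, ARR6 and BT2 on none. Despite its name, PAP3 was not on the flavonoid list to which the anthocyanin regulators PAP1 and PAP2 belong. Xylem markers did not pass (median 0.70), the guard cell genes SPCH (AT5G53210) and FAMA (AT3G24140) were 1.80-fold and 1.75-fold higher, the epidermal regulator ATML1 (AT4G21750, above background on 2 of 3 S3 arrays) was 2.86-fold lower and the epidermal gene PDF1 (AT2G42840, above background on 2 of 3 WT_S1 arrays) 2.1-fold higher, and the cell cycle gene CDKB2-1 (AT1G76540) lower and not above background at S3 (adjusted p = 0.00892). In total 4140 genes passed, 1417 higher and 2723 lower, of which 792 and 1306 at least 2-fold (limma). The median tested gene was at -0.18, and after centring 1859 were higher and 1911 lower, or 970 and 881 at 2-fold. Among genes above background on all 9 arrays 480 were higher and 416 lower at 2-fold. Without LEC2_S3 replicate 1, 2 or 3, 1364, 6710 and 2012 genes passed, and without WT_S1 replicate 1, 2 or 3 2228, 1598 and 2559. With replicate 2 as the only S3 array 540 passed, 184 higher and 356 lower.

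Of the 34 genes higher in green transgenic leaves than in the wild type, 32 were also higher in the yellow transgenic leaves, and 2 of the 3 lower genes were also lower. Independent lists of these sizes would share 2.73 higher and 0.463 lower genes, and simulated unchanged groups against the same controls shared 0 on average over 100 simulations. Groups without change give hardly any calls, so that 0 does not show how many calls shared controls add. CYP704B1 and AT2G28200 were the 2 exceptions among the rises. Across genes, which are not independent replicates, the covariance of the log2 fold changes was 0.214, against 0.0553 in the simulations, and their correlation 0.445, against 0.5003 in the simulations. The 3 wild-type arrays could not be split with at least 2 in each part, so part of the excess may come from the shared controls.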

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

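The share of lower calls in the brightest genes and the centring of the arrays were tests chosen only after the data had been seen, although the outcome named for centring was written before its result was read. How both tests are read was settled after their values were known.

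Random control probes, which are no measured genes but set the background threshold of each array, were brighter on the S3 arrays than on the wild-type arrays after normalisation. Their 95th percentile (log2) was 10.57, 9.91 and 10.51 on LEC2_S3 replicates 1, 2 and 3, against 9.41, 9.48 and 9.20 on WT_S1 and 9.44, 9.28 and 9.57 on LEC2_S1. Normalisation gives every array the same spread of values, so the random probes took a higher place among all probes on each S3 array. Replicates 1 and 3 had the lowest ratio of median gene to median random signal, 3.57 and 3.34. Replicate 2 did not stand low by that ratio (7.63), but against the 95th percentile of the random probes all 3 were below the S1 arrays, at 0.868, 1.22 and 0.898 against 1.54 or more on those with raw signal. Why the random probes stood higher was not tested. Through the thresholds their level enters the choice of tested genes and every bound of at least N-fold. No S3 array shared a scan batch with an S1 array, so stage and batch cannot be told apart.

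In LEC2_S3 against LEC2_S1, 3584 genes were lower and 1370 higher. Weak signal on the S3 arrays may lower genes by an amount that depends on their brightness. The tested genes were put in 4 groups of equal size by brightness. From the dimmest to the brightest, the median log2 fold changes were -0.34, -0.26, -0.20 and -0.12, so dim genes among them fell more. The filter may add to this, since thresholds were higher on the S3 arrays and a dim gene could pass through its S1 arrays. With no filter on dim genes the median over all genes was -0.05, against -0.20 in the tested genes. Of the calls 72.3% were lower in the brightest group and 68.4% in the dimmest. The excess thus lay at both ends, and weak signal stays open. Scaling stays open too. With each array centred on the median of the tested genes 57.3% of the calls were lower, but centring brings the calls nearer to balance whatever the cause. Without centring, cyclic loess gave 1670 higher and 3296 lower genes and median scaling 920 and 4156. The excess also depends on the filter: no filter on dim genes gave 2887 higher and 4149 lower (1461 and 1889 at 2-fold), and genes above background on all 9 arrays 1062 and 2250 (502 and 567 at 2-fold). A true excess of falling transcripts as leaves yellow, which the change of stage offers as the biological explanation, was not tested and stays open.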

How the results depend on the processing

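Settings chosen after the data were seen were the centring of each array, S3 replicate 2 as the only S3 array, the replicate block with exchanged numbers and the values within the scan batch of 1 array per genotype. No named gene or list past the threshold changed direction in a setting run for it; other called genes were not followed. Apart from the results below, the total counts stayed within 1.5 times their values, and LEC2 stayed past the threshold at S1 and at S3 against the wild type. Over all settings, 2949 results of single named genes kept their side of the threshold, 350 fell short of it and 36 newly passed; for lists these were 628, 32 and 12, and 3 results of lists not called before passed in the other direction. The cause was not tested unless stated.

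For LEC2_S1 against WT_S1 (37 genes, all at least 2-fold), cyclic loess gave 22 genes (22 at 2-fold) and a mean of probes 56. Only genes above background on all 9 arrays gave 1 gene (1 at 2-fold), since this filter removes genes absent from the wild type. Array weights gave 3459 (977 at 2-fold), the 6 arrays alone 200 (167), scan batch as a block 142 (125) and the batch of 2 arrays per genotype 9 (9). Leaving out 1 replicate gave 22 to 30 genes, and 22 to 30 at 2-fold.

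For LEC2_S3 against LEC2_S1 (4954, 2371 at 2-fold), array weights gave 10325 (4272), the 6 arrays alone 3072, and replicate 2 as the only S3 array 72 (72). Genes above background on all 9 arrays gave 1069 at 2-fold (502 higher and 567 lower, against 800 and 1571), from fewer genes tested. No filter on dim genes gave 2887 higher and 4149 lower genes (1461 and 1889 at 2-fold), against 1370 and 3584. Leaving out 1 replicate gave 2014 to 7659 genes, and 1312 to 3963 at 2-fold. For LEC2_S3 against WT_S1 (4140, 2098 at 2-fold), array weights gave 10343 (3821), the 6 arrays alone 2506, scan batch as a random block 2666, and replicate 2 as the only S3 array 540 (517). The filter on all 9 arrays gave 2641 (896), at 2-fold 480 higher and 416 lower against 792 and 1306. No filter gave 2763 higher and 3164 lower (1417 and 1557), against 1417 and 2723. Leaving out 1 replicate gave 1364 to 6710 genes, and 1007 to 3345 at 2-fold. The array weights did not converge; they ran from 0.179 for S3 replicate 2 to 5.77 for WT_S1 replicate 2, the array with processed values.

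LEC2 in LEC2_S3 against LEC2_S1 (1.34, adjusted p = 0.063) passed with normexp background (1.35, adjusted p = 0.0478), no background correction (1.35, adjusted p = 0.0453), median scaling (1.53), cyclic loess (1.70), a mean of probes (1.46), centring (1.49) and array weights (1.96). Leaving out 1 replicate gave 0.80 to 1.73.

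Of 9, 7 and 5 lists called in the 3 comparisons, 0, 0 and 0 were called with an estimated correlation. Fry, which does not set a list against other genes, called 3 at S1 and 6 in each of the other comparisons. Those at S1 were storage proteins and oil body proteins (fry adjusted p = 7.92e-04 each) and the seed maturation regulators, which include LEC2 (fry adjusted p = 0.007). The other lists that camera called at S1 did not pass (fry adjusted p from 0.143 to 0.51). For LEC2_S3 against WT_S1, median scaling called 8 lists and replicate 2 as the only S3 array 8. In these 2 settings photosynthesis had medians of 0.37 and 0.14, against -0.15. With replicate 2 alone jasmonate genes in LEC2_S3 against LEC2_S1 stood at -0.80, against 0.49, and autophagy genes in LEC2_S3 against WT_S1 at 0.52, against -0.02. Median scaling moved the median of all tested genes from 0.06 to 0.18 at S1.

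Replicate numbers do not pair the arrays: deviations of arrays with the same number correlated across genes at -0.33, 0.04 and -0.61 at S1. With other numbers the values ran from -0.53 to 0.64. LEC2_S1 replicates 1, 2 and 3 correlated most with WT_S1 replicates 2, 3 and 1, at 0.36, 0.59 and 0.64. Each of these pairs shared a scan batch. Deviations from a group mean cancel out within the group, so the values depend on each other. A pairing under these other numbers stays open, and no fit used these pairs as blocks. A replicate block gave 26, 3200 and 2263 genes in the 3 comparisons, and 31, 4351 and 3459 with WT_S1 numbers 2 and 3 exchanged. The weak signal over background on the S3 arrays, most of all replicates 1 and 3, limits what can be seen among dim genes.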

Other observations

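Tests chosen only after the results were seen were the comparison with genes of like brightness (its bounds set with the values in hand), the CYP704B1 level at S3 over all probes and in single probes, all tests of type-A response regulators, the test of pseudogenes and the splits of the arrays. The test of response regulators at S1 and that of like brightness were added after the first test of each kind had been read. The spread allowed for in the test of time of day, and the use of the background bound for CYP704B1, were added after their values were known.

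PR1, a marker of salicylic acid signalling, had an SD of 2.99 (log2, n = 3) in WT_S1 against 0.28 in LEC2_S1. The median of the whole defence list varied in both groups, at -0.95, 0.01 and 0.84 on the WT_S1 arrays and 0.51, 0.76 and -0.57 on the LEC2_S1 arrays, relative to the WT_S1 mean. ASN1 stood at 13.47, 12.01 and 9.27 on the 3 wild-type arrays.

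Clock genes moved both ways in the yellow leaves, LHY and CCA1 up and ELF3, GI, LUX and PRR5 down. Harvest at another time of day could shift morning genes against evening genes outside the clock list. Their medians differed by -0.031, with 9 morning and 6 evening genes tested. The morning genes went both ways, and the means were -0.08 and -0.56 with an SE of 0.35 for a difference, so time of day stays open. Weak S3 signal that moves genes by their brightness could part the clock genes if it lowered bright genes more than dim ones. Those that fell were brighter at S1 by 2.85 (log2). That gap met the outcome written beforehand for weak signal. A second condition, that genes of like brightness part the same way, was added after the gap was known. Genes of like brightness did not part that way. Their medians lay at -0.16 to -0.24 beside the clock genes that fell and at -0.13 and -0.25 beside LHY and CCA1. The means of these medians differed by -0.023 (SE 0.055). Over all tested genes the dim ones fell more, though the filter on dim genes may have added to this. The clock genes themselves had means of -1.45 and 1.18. This argues against a movement by brightness, while an effect of weak signal on single genes, whatever their brightness, stays open. A change of the clock with leaf stage was not tested and stays open.

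CYP704B1 was high in green transgenic leaves and below background in the other groups. Cross-hybridisation with a transcript that follows LEC2 could explain the gene's value if it stayed up at S3. There the gene summary lay below background, so its fall is known only to be at least 1.10 (log2), and this bound is too small to decide. Probes 2 to 6 had mean log2 levels between 11.28 and 13.14 in LEC2_S1 and between 4.93 and 7.95 at S3. In the wild type they lay between 4.53 and 8.26. LEC2 itself did not fall at S3, so for these probes the values argue against a transcript that follows LEC2, although levels below background are imprecise. Probe 1 of its 6 probes fell by only 0.73, to 11.33 against 8.03 in the wild type, which leaves cross-hybridisation open for that probe alone. A stray probe could not account for a rise in 6 of its 6 probes. Different transgenic lines at the 2 stages may differ by an insertion near this gene; 1 of the 10 nearest tested genes fell with it, and an insertion acting on 1 gene cannot be told apart from an effect of stage. AtNAP, whose promoter drives the transgene, lies directly beside CYP704B1 among the tested genes. AtNAP itself had a log2 fold change of 1.04 at S1 (adjusted p = 0.551, limma). Between the stages it had 0.99 (adjusted p = 0.284, limma). What this position means for CYP704B1 was not tested.

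Cytokinin response may be lower in the transgenic leaves, a hypothesis drawn from the fall of ARR5. Without ARR5, 6 of 6 tested type-A response regulators had lower values at S1 (median -0.77, camera p = 1.475e-04 at the preset correlation, p = 0.0938 with an estimated correlation), which leaves it open. Between the stages the 7 tested regulators did not stand apart from other genes (camera p = 0.921 at the preset correlation, p = 0.961 with an estimated correlation). In LEC2_S3 against WT_S1, which joins stage and transgene, 4 of the 7 passed, all lower, with ARR5 among them. The median of the 7 was -1.51 (camera p = 0.00237 at the preset correlation, p = 0.164 with an estimated correlation).

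Pseudogenes may be over-represented among the rises at S1, a hypothesis drawn from AT3G30833. Without that locus they were 2 of 33 genes (6.06%) against 426 of 17597 others (2.42%), with an odds ratio of 2.60 (95% interval 0.301 to 10.3; Fisher's exact test, two-sided p = 0.191), too few to decide.

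For each of the 3 comparisons there are 10 splits of the 6 arrays, too few for a share under 0.05. The real split, 1 of the 10, gave 37 genes in LEC2_S1 against WT_S1, 4954 in LEC2_S3 against LEC2_S1 and 4140 in LEC2_S3 against WT_S1, and the highest of the other splits gave 0 in each. Every other split mixes arrays of both real groups, so a true difference enters its spread and leaves few calls. That 0 therefore does not show what chance alone would give.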
